A study of Schizosaccharomyces pombe with 36 samples.

How the data were processed

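The 36 libraries come from polymerase usage sequencing of Schizosaccharomyces pombe. Per the labels' protocols, cells were grown to log phase in rich medium, genomic DNA was cleaved with alkali where ribonucleotides had been left in it, and fragments were selected by size before sequencing. Each strain carries a mutant catalytic subunit of DNA polymerase delta (the cdc6 gene) or epsilon (cdc20) that leaves more ribonucleotides in the strand it makes. Per the labels, there are 9 conditions, each with 2 libraries for each polymerase: wild type, rif1 deletion, stn1-226 and stn1-226 rif1 deletion at 25 °C and at 34 °C, and taz1 deletion with no temperature given.

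Strain backgrounds differ between genotypes, per the labels. Wild type and taz1 deletion strains are listed with rnh201-RED, ade6-704 and ura4-D18. The rif1 deletion strains are listed with an rnh201 deletion, ade6-704 and ura4-D18. The stn1-226 strains and those with the added rif1 deletion carry an rnh201 deletion with another marker, polymerase alleles between lox sites, and no ade6-704. A comparison with wild type therefore also compares backgrounds, whereas stn1-226 rif1 deletion and stn1-226 share theirs. Each condition and polymerase is 1 strain as labelled, so replicates may be technical, and every p-value measures only the spread between samples.

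The deposited values are counts of fragment ends per bin of 300 bp, with 1 file per strand and library, 72 in all; bin width and strand come from the file names. The values are whole numbers with unequal totals, so no scaling had been applied to the deposited counts. Per the submitters' processing notes the reads were aligned with Bowtie2. Its version, its settings and the genome build are not given in the sources used here. The number of bins per chromosome differs between libraries, so the submitters used more than 1 reference sequence: replicate 1 of each condition other than taz1 deletion has 8084 bins on chromosome III where replicate 2 has 8177, and the taz1 deletion libraries have 7843. The assembly used here for coordinates and genes is named ASM294v3 in its annotation, which is not known to be the submitters' build. Bins were placed on it by trial offsets, regressing ends on base content. The best placement explained 13.7 to 21.6% of the variance of the detrended ends, against at most 1.14% elsewhere; for wild type 25 °C replicate 2 it explained 2.27 to 2.60%, against at most 0.99%. The taz1 deletion bins start 50000 bp inside each chromosome, and the chromosome III bins of replicate 1 start at 15000 bp.

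Per library, 3 measures were computed. The initiation step is the log2 ratio of ends on the strand and flank labelled by forks leaving a site to ends on the opposite strand and flank, with 10 bins on each side. Sites were local maxima of the step over 10 bins above a threshold of 0.33 log2, which is 20% of the 99th percentile, in the pooled libraries, and 536 sites were covered in all libraries except those of taz1 deletion (520 with them). Total ends are both strands summed in blocks of 50 kb counted from the chromosome ends (255 blocks, 250 with taz1 deletion), normalised by TMM. Fork direction is the log2 ratio in the same blocks of ends labelled by forks moving toward the chromosome end to ends labelled by forks moving toward the centromere. The 4 terminal blocks of chromosomes I and II were also summed into 1 value.

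Tests were edgeR 4.0.16 quasi-likelihood tests in R 4.3.3, for the mean of the Pol delta and Pol epsilon differences, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p; values with a mean under 10 ends per library were left out. For steps and fork direction the 2 opposed counts of each library were columns and the library a block. All groups share 1 estimate of the spread, with 16 residual degrees of freedom. The lists of sites were: within 50 kb of the ends of chromosomes I and II, 50 to 100 kb from them, within 100 kb of the ends of chromosome III, within 50 kb of a centromere, high, middle and low mean step in 3 equal parts, within 1 kb of a pair of telomere-like motifs that share 200 bp, within 1 kb of the Rif1 consensus sequence, and within 1 kb of a tRNA gene. Each list was compared with all other sites by two-sided permutation of the site values (100000 draws) and by Fisher's exact test on the calls, over 80 tests each. Sites are not independent replicates. A site that has no step in wild type is called only if a mutant raises it, so lists tied to a motif were also tested on sites called in wild type only. The mean step is that of all libraries pooled, so a site's own change moves it between the 3 parts, and these parts are not used for the comparisons with a labelled rif1 deletion. DESeq2 1.42.0 and limma 3.58.1 served as alternatives. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9.

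Measures, tests, lists, the main alternatives and the rule for naming sites and blocks were fixed before the data were examined. The rule names the terminal blocks, the centromere blocks and the block of mat1, fixed loci, at most 10 sites with the highest rise and 10 with the deepest fall among calls where every library of the test group lay beyond both control libraries of its polymerase, and at most 5 blocks of total ends each way. The nearest protein-coding gene gives a site its name, and expression of that gene was not measured. The end blocks of chromosome III stand for the rDNA flanks, since the rDNA repeats lie at both of its ends. There are 2 departures from the plan. The taz1 deletion libraries lack every terminal block of chromosomes I and II except the right end of II, so that block stands for the chromosome ends in that comparison, which used all 36 libraries on shared bins. The other comparisons used the 32 libraries without taz1 deletion, which keeps the end bins.

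After the data were examined, the fine profile of ends along chromosome I was found to split the libraries into 3 classes that run across genotypes. Class P holds rif1 deletion 25 °C, replicate 1 of every 34 °C condition and of taz1 deletion. Class Q holds replicate 2 of every 34 °C condition, of taz1 deletion and of wild type 25 °C, and replicate 1 of stn1-226 25 °C and of libraries labelled stn1-226 rif1 deletion 25 °C. Class R holds wild type 25 °C replicate 1 and replicate 2 of stn1-226 25 °C and of libraries labelled stn1-226 rif1 deletion 25 °C. Alternatives added at that stage were the class as a block, limma on pairs of Pol delta and Pol epsilon libraries, the same pairs divided by the SD of their strand polarity along the genome, the removal of doubted libraries (wild type 25 °C replicate 2 and rif1 deletion 34 °C replicate 2), all 36 libraries in the fit of the sites, and a test of every place of the 2 motifs in the sequence against 100000 joint shifts along the genome (places within 1 kb of the one before merged, bins in all libraries but taz1 deletion). The division by polarity was also applied to the motif lists of taz1 deletion at sites called in wild type only. Alternatives fixed earlier were the tool, the flank, the site calling, the filter on low counts, the block size, the normalisation, the polymerase, the groups in the fit, the control of taz1 deletion, a block for the replicate number, and each library left out in turn.

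The fits were tested on simulated counts. For rif1 deletion at 25 °C, 200 of 536 sites were changed. Of these, edgeR found 80 of 100 changed by 1 log2 and 31 of 100 changed by 0.5 log2, with 1 false call. The list test passed its threshold in 50 of 50 simulated lists shifted by 1 log2 and in 2 of 50 without a shift. Both simulations drew noise independently for each site. In the real libraries, deviations of same-numbered libraries correlated across sites, at r from -0.90 to 0.89. The real rates of detection and of false calls may therefore differ.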

Results

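Polymerase usage sequencing maps which replicative polymerase made each strand of the genome. Pol epsilon makes most of the leading strand and Pol delta most of the lagging strand, so ends that switch strand along a chromosome mark a site of initiation, and the strand bias between sites gives the direction of forks. The 36 libraries of Schizosaccharomyces pombe cover 9 conditions with 2 Pol delta and 2 Pol epsilon libraries each. The conditions address 3 proteins of chromosome ends. Stn1, with Ten1, protects telomeres and is affected by the temperature-sensitive stn1-226 allele. Taz1 is the shelterin protein that binds telomere repeats. Rif1 sits at telomeres and at origins, where it restrains firing. Libraries held 2211561 to 25702454 ends. The median bin held 39 ends in the least deep, Pol delta replicate 2 of the libraries labelled stn1-226 rif1 deletion at 25 °C, and 575 in the deepest, Pol epsilon replicate 1 of taz1 deletion. The least deep library still held 44956 ends in the 4 terminal blocks of chromosomes I and II.

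The deleted genes were examined first. Over taz1 (SPAC16A10.07C, chromosome I 3091021 to 3093260) the 4 taz1 deletion libraries held 0 ends, which allows at most 0.0025 times the median bin by counting error, and the highest mean of the other conditions was 1.07 ± 0.11 in stn1-226 34 °C (SD, n = 4). Over rif1 (SPAC6F6.17, chromosome I 2766273 to 2770704) the rif1 deletion libraries held 0.018 ± 0.016 times the median bin at 25 °C and 0.012 ± 0.0076 at 34 °C (SD, n = 4). The libraries labelled stn1-226 rif1 deletion held 1.10 ± 0.12 and 1.09 ± 0.08 there (SD, n = 4), against 1.21 and 1.11 in stn1-226 and 1.13 and 1.08 in wild type. Ends over the whole rif1 gene thus go against the deletion their labels state, and any direction drawn from them rests on the label. Over rnh201, the catalytic subunit of RNase H2, the stn1-226 strains held 0.09 to 0.10 and the others 0.18 to 0.22. Wild type was low at 0.19 ± 0.06 (25 °C) and 0.21 ± 0.03 (34 °C), although its labels name the rnh201-RED allele. Over ura4, wild type 25 °C replicate 2 held 1.27 (Pol delta) and 0.29 (Pol epsilon) although its label states ura4-D18. Replicate 1 held 0.0020 and 0.0025.

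**Figure D1:**
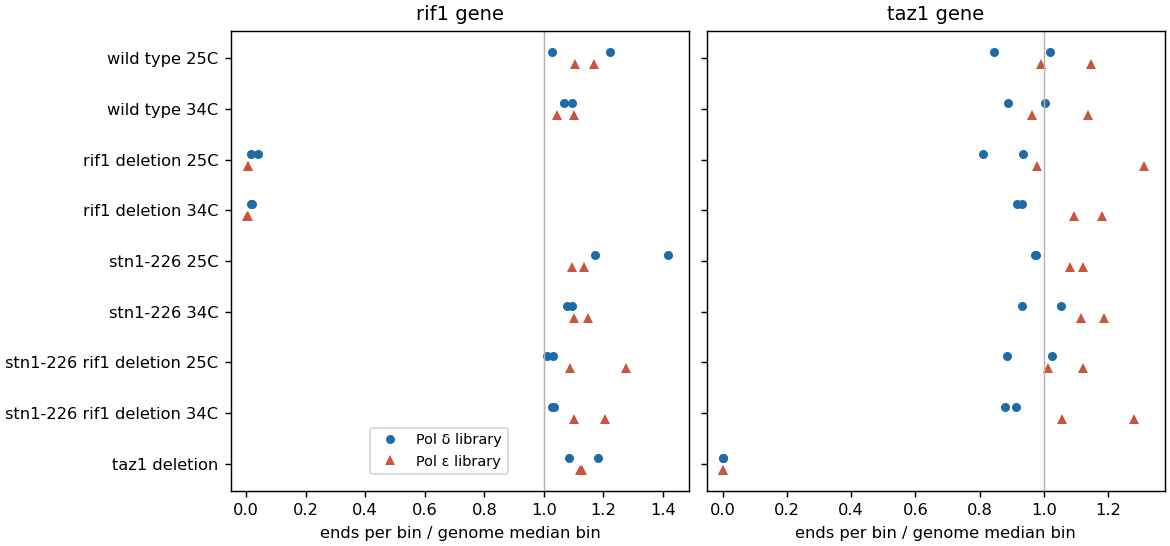
Ends per bin over the rif1 gene (left) and the taz1 gene (right), relative to the library's median bin (horizontal axis), for each condition (vertical axis), with 1 circle per Pol delta and 1 triangle per Pol epsilon library. The rif1 gene averages 0.018 in rif1 deletion 25 °C and 1.10 in libraries labelled stn1-226 rif1 deletion 25 °C.

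The rif1 deletion was compared with wild type to see which origins Rif1 restrains. At 25 °C, initiation rose at 27 sites and fell at 12 of 536. The site beside dpe2 (chromosome III 2308801, 944 bp from the gene SPCC965.12) rose by 2.10 log2 (SE 0.23, adjusted p = 3.7e-06). Its step was 1.80 ± 0.02 in the deletion and -0.30 ± 0.08 in wild type (SD, n = 2 pairs). The site beside SPBC3B8.08 (chromosome II 3379501) rose by 2.10 log2 from a step of 0.08 in wild type. The site beside erg1, which encodes squalene epoxidase (chromosome II 891601), rose by 1.85 log2 from 0.05. The site beside klp3, a kinesin-like protein (chromosome I 4706401), rose by 1.72 log2 from 0.21. The sites beside pas1 (1.85 log2), ubc1 (1.82 log2), yea4 (1.78 log2), mug114 (1.61 log2), nif1 (1.56 log2) and SPAC23H4.05C (1.46 log2) rose as well. The deepest fall was beside scl1, a proteasome subunit (chromosome II 957301, -0.94 log2, SE 0.19, adjusted p = 0.0032). It was followed by rpc1, the largest subunit of RNA polymerase III (-0.76 log2), a site in centromere II whose nearest gene is rpb1 (chromosome II 1619101, -0.75 log2) and utp21, a U3 snoRNP protein (-0.67 log2). Smaller falls lay beside lmb1 (-0.65), bit2 (-0.55), hsp16, a small heat shock protein (-0.54), SPAC922.03 and hel2 (-0.47 each), and SPBC1348.10C near the left end of chromosome II (-0.40). Of these named calls those at lmb1 (without 4 of the 8 libraries in turn), bit2 (1), hel2 (5), SPAC922.03 (7), SPBC1348.10C (7) and SPAC23H4.05C (1) were lost when a single library was left out, and the other 14 were kept. The edgeR test gave 85 sites at an unadjusted p under 0.05. The rif1 deletion 25 °C libraries share no class with wild type 25 °C, so no value within a class can be given. With the class as a block 109 sites passed (27 rose, 82 fell), and with pairs scaled by their polarity 202 passed (49 rose, 153 fell). That scaling moved the median change of all sites from -0.05 to -0.16 log2. With Pol epsilon libraries alone 0 sites passed. With sites called in wild type only, where a site without a step in wild type cannot be called, 24 passed (14 rose, 10 fell).

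At 34 °C, 9 sites rose and 16 fell. Those that rose included klp3 (1.53 log2, adjusted p = 5.3e-05, from 0.13 ± 0.06 to 1.66 ± 0.46, SD, n = 2 pairs), dpe2 (1.46), ubc1 (1.46), yea4 (1.45), SPBC3B8.08 (1.41), mug114 (1.20), erg1 (1.13) and coa6 (chromosome II 2339101, 0.93). Those that fell included scl1 (-0.95 log2, adjusted p = 0.0048), SPAC4A8.14 (-0.92), mad1, a spindle checkpoint protein (-0.89), utp21 (-0.85), abo2 (-0.81), msd1 (-0.80), rpc1 (-0.79), lmb1 (-0.75), glm1 (-0.61) and snu13 (-0.58). Leaving out single libraries ended the calls at SPBC3B8.08 (without 1 of the 8 libraries in turn), erg1 (5), coa6 (3), SPAC4A8.14 (6), mad1 (4), abo2 (4), msd1 (6), lmb1 (3), glm1 (4) and snu13 (5). At the called sites the pairs of class P gave 1.59 ± 0.31 for the rises and -0.46 ± 0.15 for the falls, and those of class Q gave 0.90 ± 0.33 and -0.97 ± 0.27 (SD across 9 and 16 sites). All 25 had the same direction in both classes. The sites were called from these same pairs, so that agreement was largely fixed by the choice of sites. Across the 536 sites, which are not independent replicates, the changes at 25 °C and 34 °C, which share no library, had r = 0.84 (Spearman 0.66). The interaction of temperature with rif1 deletion passed at 0 sites in edgeR and at 2 sites at an unadjusted p under 0.05, so the difference between 39 calls at 25 °C and 25 at 34 °C is not shown to be one between temperatures. The strand polarity of rif1 deletion 34 °C replicate 2 had an SD of 0.67 where replicate 1 had 1.10. The count moved to 163 sites without rif1 deletion 34 °C Pol epsilon 1, to 13 without rif1 deletion 34 °C Pol delta 2, wild type 34 °C Pol delta 1 or wild type 34 °C Pol delta 2, and to 11 without wild type 34 °C Pol epsilon 2. It was 93 with DESeq2 (22 rose, 71 fell), 229 with the class as a block (34 rose, 195 fell), 71 with limma on pairs and 3 with only the groups compared. With scaled pairs 137 passed and the median of all sites moved from -0.24 to -0.10 log2, and 32 passed without the doubted libraries (28 rose, 4 fell). With sites called in wild type only 18 passed (0 rose, 18 fell), so the rises at 34 °C rest on sites called with the mutant libraries pooled in.

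In stn1-226, initiation was compared with wild type at 25 °C and at 34 °C. The labels give the allele as temperature-sensitive. No site passed at either temperature. With edgeR 0 sites passed at 25 °C (11 at an unadjusted p under 0.05) and 0 at 34 °C (2 unadjusted); DESeq2 gave 0 at both (15 and 3 unadjusted), as did limma on pairs (25 and 1 unadjusted). Of the 10 named rises of rif1 deletion at 25 °C, 8 are on the list with the Rif1 consensus, and those beside SPBC3B8.08 and pas1 are not. The list depends on the choice of sites, as given below. In stn1-226 the mean change of that list differed from that of the other sites by -0.10 log2 at 25 °C (permutation adjusted p = 0.20) and -0.04 at 34 °C (adjusted p = 0.32). With the 3 consensus sites called in wild type only it was 0.00 at 25 °C (adjusted p = 1.0) and -0.14 at 34 °C (adjusted p = 0.032). At the early origin ars1, beside hus5 (chromosome I 1095901), the values were 0.10 and -0.12 log2. Beside tlh1 and tlh2, the telomere-linked helicase genes, they lay between -0.22 and 0.05 log2. The median change of all sites at 25 °C was 0.13 log2, and -0.06 with scaled pairs. In data of the 25 °C comparison simulated with noise independent between sites, the same test found 88 of 100 sites changed by 1 log2. It found 36 of 100 changed by 0.5 log2, so smaller changes at single sites were mostly not detectable. Background genotype differs between the compared strains.

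The libraries labelled stn1-226 rif1 deletion were compared with stn1-226 of the same background. At 25 °C 23 sites rose and 12 fell; at 34 °C 29 rose and 6 fell. The sites beside dpe2 (2.04 log2, adjusted p = 5.1e-06), yea4 (2.03), mug114 (1.96), SPBC3B8.08 (1.95), klp3 (1.78), erg1 (1.71), ubc1 (1.69), pas1 (1.52), SPAC23H4.05C (1.49) and SPAC25A8.03C (1.31) rose at 25 °C. At 34 °C the rises were yea4 (2.04), SPBC3B8.08 (1.92), klp3 (1.88, SE 0.19, adjusted p = 1.8e-06), dpe2 (1.83), pas1 (1.75), ubc1 (1.74), mug114 (1.69), erg1 (1.58), SPAC23H4.05C (1.39) and the site beside rpa12, an RNA polymerase I subunit (1.28). The site beside scl1 fell by 1.12 log2 at 25 °C (SE 0.20, adjusted p = 0.00061) and by 0.88 log2 at 34 °C. Further falls at 25 °C lay beside mad1 (-0.75), utp21 (-0.74), hsp16 (-0.71), SPAC977.14C near the left end of chromosome I (-0.63), SPAC922.03 (-0.59), rpc1 (-0.52), SPCC965.09 (-0.52) and his4 (-0.48), and at 34 °C beside bit2 (-0.55), glm1 (-0.54), rpc1 (-0.53), hsp16 (-0.43) and SPCC965.09 (-0.43). Leaving out single libraries ended calls at 25 °C beside pas1 (without 4 of the 8 libraries in turn), SPAC23H4.05C (4), mad1 (7), SPAC922.03 (4), rpc1 (6), SPCC965.09 (4) and his4 (5). At 34 °C it ended those beside SPAC23H4.05C (4), rpa12 (8), bit2 (3), glm1 (7), rpc1 (7), hsp16 (6) and SPCC965.09 (8). In all 4 comparisons with a labelled rif1 deletion, which share no libraries, 9 sites rose: dpe2, yea4, coa6, ubc1, SPBC3B8.08, erg1, mug114, klp3 and a site beside cuf1 that was named after its values were seen. Independent lists of these lengths would share 0.0011. The sites were called with the mutant libraries pooled in, so the lists are not independent and that value does not measure chance. With sites called in wild type only, 0 rose in rif1 deletion at 34 °C, so no rise could be shared by all 4 comparisons. In all 4 comparisons 4 sites fell, beside scl1, rpc1, hsp16 and SPCC965.09. Across the 536 sites, the change at 25 °C and that of rif1 deletion against wild type at 25 °C, which share no library, had r = 0.89 (Spearman 0.77), and at 34 °C r = 0.84 (Spearman 0.61). The sites of these libraries thus changed along with those of rif1 deletion although the rif1 gene was covered.

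Within classes at 25 °C the rises averaged 1.35 ± 0.56 in class Q and 1.14 ± 0.46 in class R, and the falls -0.57 ± 0.23 and -0.78 ± 0.16 (SD across 23 and 12 sites). At 34 °C the rises averaged 1.20 ± 0.46 in class P and 1.28 ± 0.36 in class Q, and the falls -0.68 ± 0.21 and -0.44 ± 0.13 (SD across 29 and 6 sites). The sites were called from these same pairs, so the class averages are no separate support for the calls. Unadjusted, edgeR gave 75 sites at 25 °C and 58 at 34 °C. With pairs scaled by polarity 102 sites passed at 25 °C (44 rose, 58 fell) and 123 at 34 °C (45 rose, 78 fell). With the class as a block the counts were 106 (44 rose, 62 fell) and 70 (46 rose, 24 fell), and with Pol epsilon libraries alone 0 and 4. With sites called in wild type only they were 21 (8 rose, 13 fell) and 23 (16 rose, 7 fell), so the excess of rises at 25 °C depends on sites called with the mutant libraries pooled in. Leaving out stn1-226 25 °C Pol delta 2 or Pol epsilon 1 of the libraries labelled stn1-226 rif1 deletion 25 °C left 22 sites and leaving out Pol epsilon 2 of the latter left 23. At 34 °C the count was 23 without stn1-226 Pol epsilon 2 or without Pol delta 2 or Pol epsilon 1 of the libraries labelled stn1-226 rif1 deletion.

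**Figure D2:**
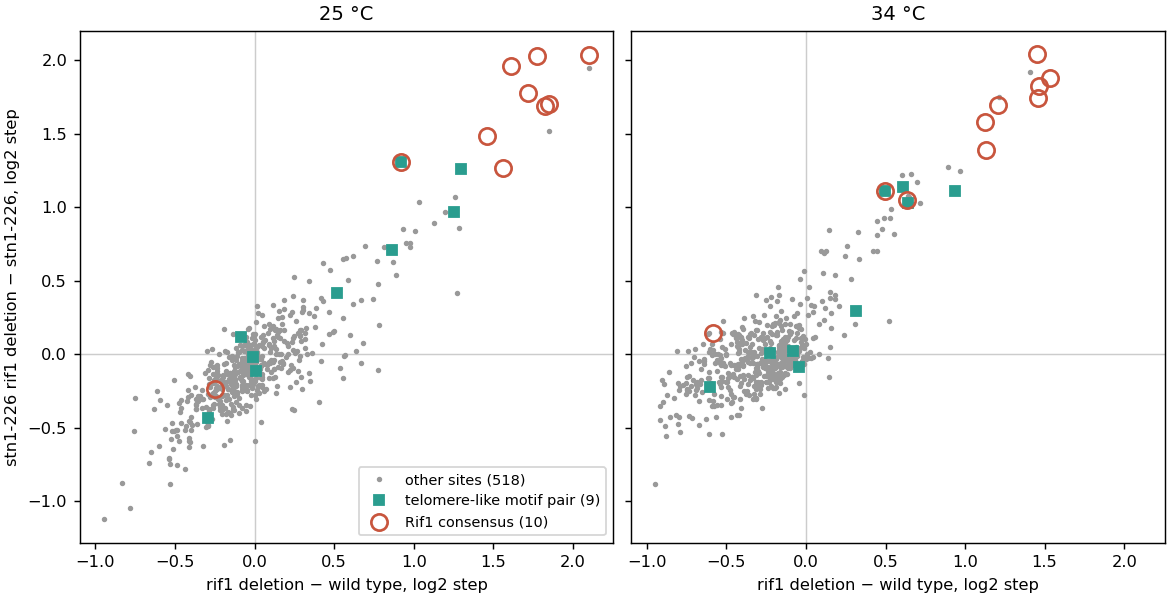
Change of the initiation step (log2) in rif1 deletion against wild type (horizontal axis) and in libraries labelled stn1-226 rif1 deletion against stn1-226 (vertical axis) at 25 °C (left) and 34 °C (right), with 1 point per site, squares for the 9 motif-pair sites and rings for the 10 Rif1 consensus sites. At 25 °C 9 of the 10 rings lie in the upper right, and the dpe2 site stands at 2.10 and 2.04 log2.

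Among the lists of sites, the 10 sites within 1 kb of the Rif1 consensus stood apart in the comparisons with a rif1 deletion. In rif1 deletion 9 rose at 25 °C and 6 at 34 °C. In the libraries labelled stn1-226 rif1 deletion 9 rose at each temperature. The counts adjusted over the list alone were 9 in each of the 4 comparisons. They include dpe2, erg1, ubc1, yea4, klp3, mug114, nif1, SPAC23H4.05C and SPAC25A8.03C. The mean change of the list exceeded that of the other sites by 1.46 and 1.24 log2 in rif1 deletion (25 °C, 34 °C) and by 1.58 and 1.42 in the libraries labelled stn1-226 rif1 deletion. Sites were called with the mutant libraries pooled in, so a place without a step in wild type is on the list only if it rose, and these counts and differences hold for that choice of sites alone. Of the sites called in wild type only, 3 lie within 1 kb of the consensus. Of these 2 rose in rif1 deletion at 25 °C (1.56 log2 beside nif1 and 0.92 at chromosome I 2096101, adjusted p = 0.0027 each), 0 at 34 °C (0.64 and 0.49) and 2 at each temperature in the libraries labelled stn1-226 rif1 deletion. The third (chromosome III 1342201) stood at -0.25, -0.59, -0.24 and 0.14. The difference of these 3 from the other sites was 0.79, 0.45, 0.89 and 0.77 log2, well under that of the 10 (permutation adjusted p = 0.0029, 0.026, 0.00072 and 0.0025 over 24 tests). In a test added after the data were examined, the step change was taken at the 48 places of the consensus in the sequence, whether or not a site was called there, and compared with the same places shifted together along the genome. The places exceeded the genome by 0.59, 0.46, 0.59 and 0.60 log2 (adjusted p = 0.00023, 0.00023, 0.00028 and 0.00023 over 14 tests), and 13, 10, 14 and 13 of them changed by more than 1 log2. In stn1-226 they differed by 0.04 log2 at 25 °C (adjusted p = 0.013) and -0.03 log2 at 34 °C (adjusted p = 0.0029), with none over 1 log2, and in wild type between temperatures by 0.01 log2 (adjusted p = 0.57). The 9 sites with a pair of telomere-like motifs rose at 4, 1, 4 and 4 sites in the same order (5, 3, 4 and 4 adjusted over the list alone), with differences of 0.48, 0.46, 0.53 and 0.45 log2 under the same choice of sites. Of the sites called in wild type only 8 have a motif pair, of which 3, 0, 1 and 3 rose, with differences of 0.44, 0.41, 0.48 and 0.42 log2 (permutation adjusted p = 0.0025, 0.0018, 0.0012 and 0.0025 over 24 tests). At the 164 places of the pair in the sequence the differences were 0.02, 0.04, 0.02 and 0.02 log2, past the test in rif1 deletion at 34 °C alone (adjusted p = 0.020), so a motif pair away from a site went with next to no change. In stn1-226 the list differed by -0.00 and 0.04 log2 without passing.

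Chromosome ends differed little from the rest of the genome in these 4 comparisons as far as sites go. The 15 sites within 50 kb of the ends of chromosomes I and II differed from other sites by -0.07, 0.06, -0.03 and -0.08 log2, with 1 fall at 25 °C in rif1 deletion. The 16 sites 50 to 100 kb from the ends differed by -0.08, 0.14, -0.06 and -0.12. The 7 sites within 100 kb of the ends of chromosome III differed by -0.06, -0.11, -0.09 and -0.05, and the 26 near centromeres by -0.14, -0.00, -0.03 and -0.06. No difference passed the permutation test (two-sided, adjusted over 80). Calls at 50 to 100 kb numbered 1 rise and 2 falls in the libraries labelled stn1-226 rif1 deletion at 25 °C and 0 in the other 3 comparisons. Adjusted over the list alone they were 1 rise and 2 falls there and in rif1 deletion at 25 °C, and 1 rise and 3 falls in rif1 deletion at 34 °C. Near centromeres 1 rose and 2 fell in rif1 deletion at 25 °C, the same adjusted over the list alone, and 1 rose in the libraries labelled stn1-226 rif1 deletion at 34 °C (0 alone). The fall within 50 kb of an end was 0 adjusted over its list alone. At tlh1 (chromosome I 6301) the values in the same order were -0.51, -0.53, -0.52 and -0.28 log2, with a smallest adjusted p of 0.069, and at tlh2 (chromosome II 4526401) -0.49, -0.53, -0.52 and -0.22, with a smallest adjusted p of 0.085. Both genes lie in sequence shared between chromosome ends, and their values are uncertain for that reason.

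In taz1 deletion, steps were lower at 437 of 520 sites and higher at none. The site beside bqt3, a protein of the telomere bouquet (chromosome III 369601), fell by 2.25 log2 (SE 0.31, adjusted p = 1.3e-06), from 2.74 ± 0.12 in wild type (SD, n = 4 pairs) to 0.49 ± 0.12 (SD, n = 2 pairs). Sites beside mnl1 (-2.21 log2), lsk1, a cyclin-dependent kinase (-2.08), smg1 (-2.07), ctr5, a copper transporter (-2.06), SPCC61.05 (-2.05), msm1 (-2.02), snd1 (-2.02) and rpl3402 (-1.97) fell as far. The site beside cut1, which encodes separase, fell by 1.99 log2 (SE 0.27, adjusted p = 1.1e-06). The ars1 site fell by 1.21 log2 (SE 0.15, adjusted p = 2.8e-07), the tlh2 site by 0.74 log2, and the sites nearest rif1 and taz1 by 1.66 and 1.58 log2. At the site nearest ura4 (ars3002, chromosome III 114301) the change was -0.38 log2 (adjusted p = 0.17). The flank of that site holds ura4. Over ura4 taz1 deletion held 0 ends, and wild type 0.39 ± 0.60 (25 °C) and 0.03 ± 0.05 (34 °C) times the median bin (SD, n = 4). The value at that site is therefore uncertain. By list, 176 of 177 sites of high mean step fell, 148 of 174 of middle and 113 of 169 of low mean step (177, 148 and 106 adjusted over the list alone). Near a tRNA gene 47 of 51 fell, and near a centromere 24 of 26. A site with a high step has more room to fall, and in scaled pairs, described below, 78, 17 and 10 sites of high, middle and low mean step fell. Among the 10 sites with the Rif1 consensus 2 fell. Most of these have next to no step in wild type and little room to fall, and in scaled pairs they differed from the other sites by 0.19 log2 (permutation adjusted p = 0.13). The 3 called in wild type only differed by 0.07 log2 (adjusted p = 0.90). Of the 8 with a motif pair 5 fell (difference 0.39 log2, adjusted p = 0.075), and the 7 called in wild type only differed by 0.29 log2 (adjusted p = 0.20).

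These falls go with a weak polymerase signal in the taz1 deletion libraries. Their strand polarity had an SD of 0.27 and 0.21 per pair, where wild type had 1.005 to 1.10, and their mean step was 0.28 and 0.22 against 1.15 to 1.22. Polarity of Pol delta against Pol epsilon along the genome had r = -0.20 and 0.40 in the taz1 deletion pairs and -0.51 to -0.96 in the other pairs. With each pair divided by its polarity SD, 32 sites were higher and 105 lower, and the median change moved from -0.83 to -0.11 log2. Across sites, the slope of the Pol delta step on the consensus step of the libraries was 0.31 in replicate 1 and -0.04 in replicate 2. Wild type Pol delta had 0.94 to 1.35. The division thus also enlarges values of a Pol delta library with next to no step signal, which limits every result in scaled pairs of taz1 deletion. The edgeR test gave 447 sites at an unadjusted p under 0.05, and the called sites averaged -1.01 ± 0.48 in class P and -1.10 ± 0.52 in class Q (SD across 437 sites). Those sites were called from the same libraries, so the class averages are no separate support. The labels give no temperature for taz1 deletion, and wild type at both temperatures was its control.

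Wild type at 34 °C was set against wild type at 25 °C as the background for the temperature of the mutants. No site passed: edgeR 0 (3 at an unadjusted p under 0.05), DESeq2 0 (7) and limma on pairs 0 (10). The median change of all sites was 0.02 log2. The ars3002 site differed by 0.29 log2. Its flank holds ura4, which was covered in wild type 25 °C replicate 2 and not in replicate 1, so that value is uncertain. The 10 sites with the Rif1 consensus differed from the other sites by 0.02 log2. No list passed (smallest adjusted p = 0.14), and no block passed for total ends (0 with 3 unadjusted) or fork direction (0 with 5 unadjusted). The 4 terminal blocks of chromosomes I and II stood at 0.08 log2 for total ends and -0.09 log2 for fork direction, and at -0.05 and -0.17 log2 within class Q, the only class with both temperatures (1 pair each). With Pol delta alone the direction value was 0.016 log2. In data of this comparison simulated with noise independent between sites, edgeR found 85 of 100 sites changed by 1 log2 and 36 of 100 changed by 0.5 log2.

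Total ends near chromosome ends address how fully the subtelomeres, the regions next to the telomeres, are represented when Stn1 fails. In stn1-226 at 34 °C, the 4 terminal blocks of 50 kb of chromosomes I and II held fewer ends than in wild type: -0.46 log2 (SE 0.09, adjusted p = 0.0040). Their density fell from 1.44 ± 0.19 to 1.04 ± 0.06 times the median block (SD, n = 4). By block, the change was -0.74 log2 at the right end of II (4489801 to 4539600, adjusted p = 0.00028) and -0.44 at the left end of I (1 to 50100, adjusted p = 1.8e-05). It was -0.25 at the right end of I (5529001 to 5579100, adjusted p = 0.010) and -0.17 at the left end of II (1 to 50100, adjusted p = 0.13). In windows of 5 kb, the outermost window stood at 1.83 ± 0.13 log2 over the median bin in wild type and at 0.85 ± 0.18 in stn1-226 (SD, n = 2 pairs), and the window from 20 to 25 kb at 0.31 and 0.04. The tlh2 gene held 3.37 ± 0.47 times the median bin in wild type and 1.66 ± 0.29 in stn1-226, and tlh1 3.21 ± 0.47 and 1.59 ± 0.29 (SD, n = 4). Of the bins of the 4 blocks, 472 hold 50-base words that occur elsewhere in the assembly and 195 hold none. The difference was -0.48 log2 in the former and -0.39 in the latter, or -0.37 and -0.14 with the right end of II left out. A change in reads shared between ends is therefore not ruled out as part of the fall. At 25 °C the 4 blocks stood at -0.23 log2 (SE 0.09, adjusted p = 0.90), and the interaction with temperature was -0.23 log2 (SE 0.13, adjusted p = 0.99), so the effects are not shown to differ between temperatures. Within classes the 34 °C difference was -0.57 (P) and -0.35 (Q), and at 25 °C -0.31 (Q) and -0.15 (R).

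The call for the 4 blocks at 34 °C was lost without stn1-226 34 °C Pol delta 1 (adjusted p = 0.054), with total ends as the scaling (-0.43, adjusted p = 0.067), with blocks of 100 kb (-0.30, adjusted p = 0.082), with Pol delta libraries alone (-0.28, adjusted p = 0.97) and with only the groups compared (-0.46, adjusted p = 0.10). The block at the right end of I lost its call without 4 of the 8 libraries in turn.

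**Figure D3:**
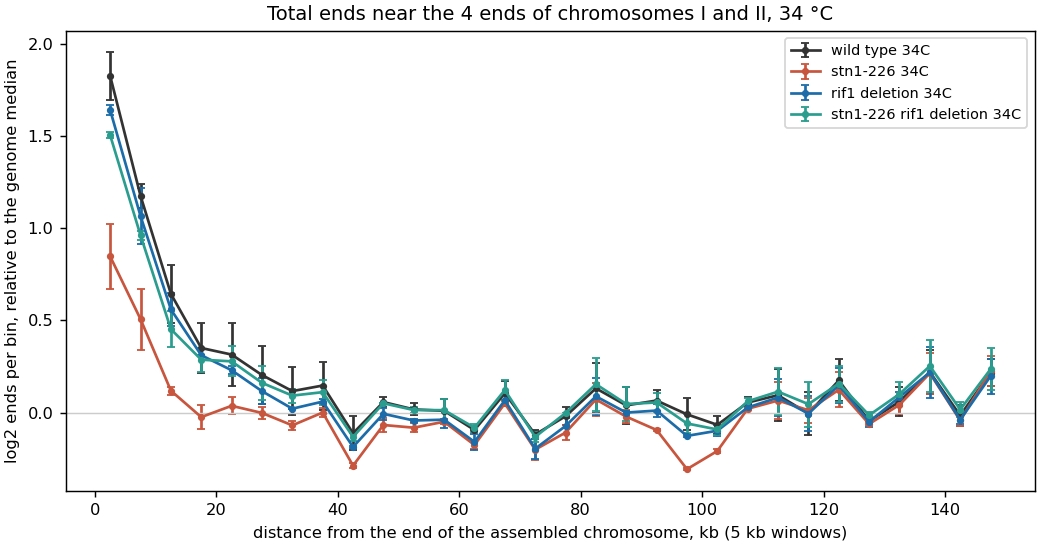
Total ends at 34 °C in windows of 5 kb from the 4 ends of chromosomes I and II (horizontal axis, kb), as log2 ends per bin relative to the genome median (vertical axis), with means and SD bars of 2 pairs per genotype. The outermost window stands at 1.83 in wild type, 0.85 in stn1-226, 1.64 in rif1 deletion and 1.51 in libraries labelled stn1-226 rif1 deletion.

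In the libraries labelled stn1-226 rif1 deletion, the left end of chromosome I held more ends than in stn1-226 at 34 °C (0.32 log2, SE 0.06, adjusted p = 0.0041), with 1.24 ± 0.08 times the median block against 1.001 ± 0.021 (SD, n = 4). The right end of II stood at 0.48 log2 (adjusted p = 0.067), the right end of I at 0.21 (adjusted p = 0.096) and the left end of II at 0.11 (adjusted p = 0.98). The outermost 5 kb stood at 1.51 ± 0.02 log2 over the median bin (SD, n = 2 pairs), between stn1-226 and wild type. The 4 blocks stood at 0.31 log2 at 34 °C (adjusted p = 0.14; 0.36 in class P, 0.24 in class Q) and at 0.15 log2 at 25 °C, where 0 blocks passed in edgeR (14 at an unadjusted p under 0.05). The difference between temperatures was not tested. The test of the 4 blocks at 34 °C passed with DESeq2 (0.30, adjusted p = 7.2e-05) and with the class as a block (0.31, adjusted p = 0.037). It also passed with the replicate number as a block (0.31) and with bins under 0.2 or over 3 times the median left out. The left end of I lost its call without 2 of the 8 libraries in turn. At 25 °C the 4 blocks stood at 0.58 log2 with Pol delta alone and at -0.31 log2 with Pol epsilon alone, opposite in direction.

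In rif1 deletion the 4 blocks stood at 0.08 log2 at 25 °C and -0.09 log2 at 34 °C, neither past the test. With Pol epsilon alone the 25 °C value was -0.30 log2, and with Pol delta alone the 34 °C value was 0.12 log2, each opposite in direction to the pooled value. Within classes the 34 °C value was -0.18 (P) and -0.02 (Q). At 34 °C, 3 blocks fell: the pair over centromere II (1600201 to 1622400, -0.49 log2, SE 0.09, adjusted p = 0.0062, and 1622401 to 1639800, -0.36 log2, adjusted p = 0.013), and the block of the rif1 gene (chromosome I 2750101 to 2800200, -0.13 log2, adjusted p = 0.016), in which the deleted gene lies. The first centromere block lost its call without 1 of the 8 libraries in turn. The other centromere block and the rif1 block lost theirs without 4 each. At 25 °C 0 blocks passed in edgeR (28 at an unadjusted p under 0.05). The end blocks of chromosome III, which flank the rDNA, are not covered in taz1 deletion, and in the other 7 comparisons neither total passed. At the left one (15001 to 50100) replicate 1 lay above replicate 2 in every condition and polymerase, and in rif1 deletion at 34 °C the SE was 0.72, so only a change well over 1 log2 could pass. With the replicate number as a block, the value there was -0.80 log2 (SE 0.23, adjusted p = 0.16), still without passing. At the right one (2402701 to 2439900) fork direction stood at -0.35 log2 in rif1 deletion at 34 °C and at -0.32 and -0.39 log2 in the libraries labelled stn1-226 rif1 deletion (25 °C, 34 °C), not past the main test (adjusted p = 0.21, 0.22 and 0.15) but past it with the replicate number as a block (adjusted p = 0.012, 0.017 and 0.0073). They also passed with the class as a block (adjusted p = 0.0080, 0.016 and 0.0043). In rif1 deletion at 25 °C the value was -0.18 log2, not past the main test (adjusted p = 0.53) or the replicate block (adjusted p = 0.18), and -0.63 log2 with the class as a block (adjusted p = 0.00075), where the 2 groups share no class. On chromosome III the replicate number goes with the reference, a difference that the main test counts as spread. Set against the control pair of the same number, the pair lay lower in all 8 pairs of these 4 comparisons, by 0.14 to 0.50 log2. The stn1-226 pairs also lay below wild type, by 0.0059 to 0.35 log2, without passing. The blocks of centromeres I and III did not pass for total ends in any comparison.

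The block of the mating-type locus mat1 (chromosome II 2089801 to 2139600) rose in stn1-226 by 0.58 log2 at 25 °C (SE 0.08, adjusted p = 5.4e-05) and by 0.78 log2 at 34 °C (SE 0.08, adjusted p = 4.5e-07). It held 1.59 ± 0.26 and 1.90 ± 0.33 times the median block, against 1.05 ± 0.12 and 1.09 ± 0.06 in wild type (SD, n = 4). The libraries labelled stn1-226 rif1 deletion held 1.84 ± 0.21 and 2.07 ± 0.32 there, not past the test against stn1-226. The rif1 deletion libraries held 1.08 and 1.10, and the taz1 deletion libraries 1.49 ± 0.54 (0.48 log2, adjusted p = 0.12). The latter mean describes neither pair: replicate 1 stood at 0.97 log2 over the median block, as high as stn1-226, and replicate 2 at 0.03, as in wild type. The labels give both the mating type of wild type. The labels give the mating type of the wild type and taz1 deletion strains and not of the others, so mating type and genotype cannot be told apart at this block.

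In taz1 deletion the only terminal block covered, the right end of chromosome II, held more ends than wild type: 0.80 log2 (SE 0.14, adjusted p = 0.0016), 3.82 ± 0.39 times the median block against 2.12 ± 0.60 and 2.31 ± 0.33 in wild type at 25 °C and 34 °C (SD, n = 4). The tlh2 gene in this block held 4.98 ± 1.24 times the median bin. The reference of the taz1 deletion libraries differs, and this confounds the value. Of the 50-base words of the block 80.5% occur elsewhere in the assembly, and 96.2% of those have a copy in sequence that the reference of these libraries lacks, so reads of other ends can fall here. In the 145 bins with shared words the difference was 0.92 log2, and in the 21 without it was 0.32 log2. In the latter the lowest taz1 deletion pair minus the highest wild type pair was -0.60 log2, so the groups overlapped. The block of the taz1 gene itself (chromosome I 3050101 to 3100200) fell by 0.09 log2 (adjusted p = 0.0040, and 0.063 without taz1 deletion Pol epsilon 2). Within classes the end block rose by 0.69 (P) and 0.72 (Q). Its call was lost with blocks of 25 kb (0.51, adjusted p = 0.37), with Pol delta alone (0.93, adjusted p = 0.19) and with only the groups compared (0.80, adjusted p = 0.21).

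Fork direction near the ends was compared to see from which side subtelomeres are replicated. In rif1 deletion at 25 °C the ratio of forks moving toward the ends to forks moving away fell in the 4 terminal blocks together (-0.41 log2, SE 0.09, adjusted p = 0.00073), and in 97 of 255 blocks it changed (47 rose, 50 fell). The left end of I fell by 0.53 log2 (adjusted p = 1.8e-07), the left end of II by 0.24 log2 and the right end of II by 0.65 log2. The right end of I stood at 0.01 log2 (adjusted p = 0.96). Here and below, reads shared between ends limit fork direction in the terminal blocks. Of their bins 472 hold sequence found elsewhere, and the 195 without it were not tested alone. The neighbouring blocks fell too, by -0.77 log2 on the right of I (5478901 to 5529000), -0.43 on the left of I (50101 to 100200, a call lost without wild type 25 °C Pol epsilon 1, adjusted p = 0.081), -0.39 on the left of II (50101 to 100200) and -0.41 on the right of II (4439701 to 4489800). Beside centromere I the ratio rose by 0.27 log2 (3779101 to 3828900, adjusted p = 0.00010), and beside centromere II by 0.20 log2 (1639801 to 1689600, adjusted p = 0.019, a call lost without 4 of the 8 libraries in turn). At 34 °C 85 blocks changed (40 rose, 45 fell), among them the left ends of I (-0.47) and II (-0.23). The neighbouring blocks stood at -0.92 log2 on the right of I (SE 0.09, adjusted p = 2.5e-07), -0.59 on the right of II, -0.50 on the left of II and -0.44 on the left of I. The 4 terminal blocks stood at -0.23 log2 (SE 0.09, adjusted p = 0.046; -0.30 in class P, -0.16 in class Q). The interaction with temperature was 0.18 log2 and did not pass. The 34 °C call was lost without any single library of the comparison other than rif1 deletion 34 °C Pol epsilon 2. It was also lost with Pol delta alone (-0.40, adjusted p = 0.084), with Pol epsilon alone (-0.07, adjusted p = 0.80), with only the groups compared (-0.23, adjusted p = 0.30), with blocks of 25 kb (-0.30, adjusted p = 0.095) and without the doubted libraries (-0.27, adjusted p = 0.054).

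In stn1-226 at 34 °C 4 blocks fell in fork direction and none rose. They were the left ends of I (-0.23 log2, SE 0.05, adjusted p = 0.018) and II (-0.24 log2, SE 0.04, adjusted p = 0.0034), and the blocks next to the right ends of I (5478901 to 5529000, -0.57 log2, SE 0.09, adjusted p = 0.0012) and II (4439701 to 4489800, -0.32 log2, SE 0.07, adjusted p = 0.0069). The call at the left end of I was lost without 4 of the 8 libraries in turn. That next to the right end of II was lost without 3. The 4 terminal blocks together stood at -0.08 log2 at 34 °C and 0.10 at 25 °C (-0.09 in P and -0.08 in Q at 34 °C, 0.03 in Q and 0.18 in R at 25 °C), neither past the test. With Pol epsilon alone the 34 °C value was 0.04 log2, opposite in direction. At 25 °C 0 blocks passed in edgeR (14 at an unadjusted p under 0.05), and the interaction with temperature passed at the left end of II (-0.30 log2, SE 0.06, adjusted p = 0.022) and at the block next to the right end of II (-0.43 log2, SE 0.09, adjusted p = 0.023).

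In the libraries labelled stn1-226 rif1 deletion at 25 °C, forks toward the ends fell in the 4 terminal blocks against stn1-226 (-0.51 log2, adjusted p = 7.6e-05; -0.49 in class Q, -0.54 in class R). The left end of I fell by 0.58 log2 (adjusted p = 4.4e-08), the right end of II by 0.85 log2 (adjusted p = 0.00078) and the left end of II by 0.28 log2, while the right end of I stood at -0.08 log2. Beside centromere I it fell by 0.15 log2 (3750001 to 3771300, adjusted p = 0.047, lost without 5 of the 8 libraries in turn). The neighbouring blocks fell by 0.73 (right of I), 0.51 (right of II), 0.50 (left of I) and 0.45 log2 (left of II). In the genome 96 blocks changed at 25 °C (42 rose, 54 fell) and 78 at 34 °C (40 rose, 38 fell). At 34 °C the left end of I fell by 0.21 log2 (adjusted p = 0.0049), and the blocks next to the right ends of I (-0.38) and II (-0.27) and the left end of II (-0.30) fell as well. The 4 blocks together stood at -0.15 log2 (adjusted p = 0.21; -0.17 in class P, -0.14 in class Q), which passed with limma on pairs (-0.15, adjusted p = 0.015) and with blocks of 100 kb (-0.22, adjusted p = 0.0076). The value of the 4 blocks also passed with the class as a block (-0.15) and with scaled pairs. The difference between the temperatures was not tested. Across the 255 blocks, which are not independent replicates, the changes in these libraries and in rif1 deletion, which share none, had r = 0.90 at 25 °C and r = 0.91 at 34 °C.

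**Figure D4:**
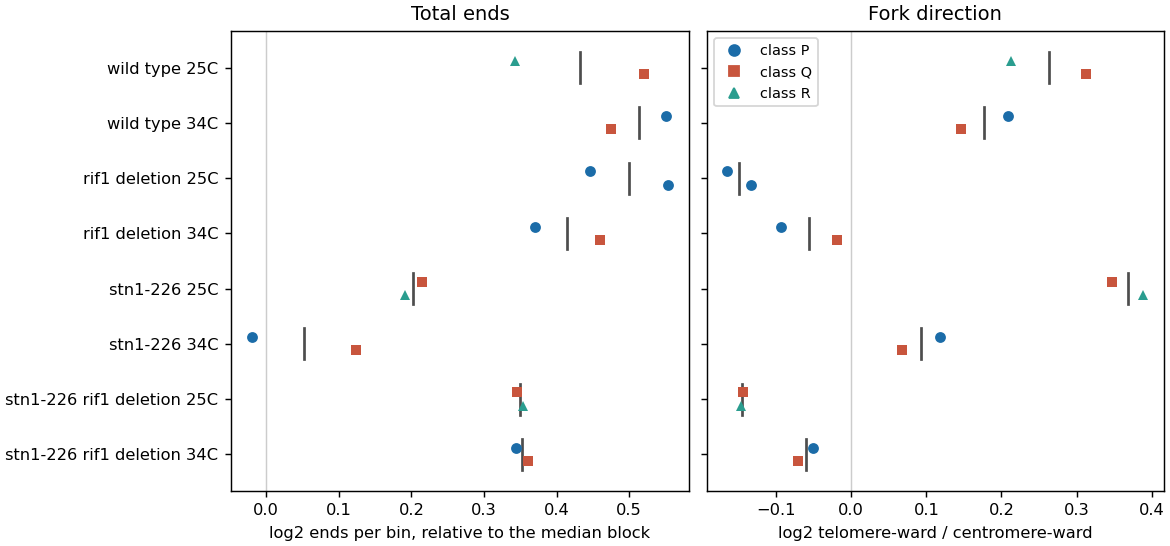
The 4 terminal blocks of chromosomes I and II in each condition, with total ends as log2 ends per bin relative to the median block (left) and fork direction as log2 telomere-ward over centromere-ward ends (right), where each symbol is a pair of libraries shaped by class and the bars are means. Total ends differ by -0.46 log2 between stn1-226 and wild type at 34 °C, and fork direction by -0.41 log2 between rif1 deletion and wild type at 25 °C.

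In taz1 deletion fork direction changed in 145 of 250 blocks (71 rose, 74 fell). Forks toward the ends fell in the blocks next to the right ends of I (-0.60 log2, adjusted p = 1.1e-06) and II (-0.52 log2, adjusted p = 1.1e-07) and next to the left ends of II (-0.40) and I (-0.39), and at the right end of II (-0.42 log2, SE 0.16, adjusted p = 0.033; -0.30 in class P, -0.42 in class Q). Around centromere II in taz1 deletion the ratio fell by 0.39 log2 (1639801 to 1689600) and rose by 0.32 log2 (1622401 to 1639800), and in centromere I it rose by 0.80 log2 (3771301 to 3779100). It also fell beside centromere I (3779101 to 3828900, -0.21 log2, adjusted p = 0.00014) and beside centromere III (1050001 to 1100100, -0.25 log2, adjusted p = 0.0022). In centromere III (1100101 to 1103400) it fell by 0.58 log2 (SE 0.24, adjusted p = 0.046, lost without 9 of the 12 libraries in turn), and beside centromere II (1600201 to 1622400) it rose by 0.18 log2 (adjusted p = 0.042, lost without 6). The weak polarity of these libraries lowers a bias of either sign. With scaled pairs these 7 values were, in order, 0.060, 0.024, 0.19, 0.079, -0.074, -0.044 and -0.015. None passed, and the values at 1639801, 3779101 and 1600201 were opposite in direction. The blocks next to the ends then stood at -0.30 (right of I), -0.55 (right of II), -0.0086 (left of II, not past the test) and -0.32 log2 (left of I), and the right end of II at -0.86 log2. Reads of other ends can fall at the right end of II, as given for total ends. The reference of these libraries therefore confounds the values there. The call at the right end of II was lost without 7 of the 12 libraries in turn. It was also lost with DESeq2 (adjusted p = 0.19), with either polymerase alone (-0.66, adjusted p = 0.057, and -0.18, adjusted p = 0.52) and with wild type 34 °C as the only control (-0.27, adjusted p = 0.23).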

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

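The tests of the explanations were chosen only after the results were seen, except for the counts over other splits of the samples. The test of the motif-pair sites in taz1 deletion was written down before its result was seen, but the scaling by polarity it uses was chosen after the data were seen.

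Groups differed by a test of the difference itself in 3 results. The change of fork direction in stn1-226 against wild type differed between 34 °C and 25 °C at the left end of chromosome II (1 to 50100) by -0.30 log2 (SE 0.06, edgeR adjusted p = 0.022). At the block next to the right end of chromosome II (4439701 to 4489800) it differed by -0.43 log2 (SE 0.09, adjusted p = 0.023). For total ends at the left end of chromosome I (1 to 50100) at 34 °C, the difference between libraries labelled stn1-226 rif1 deletion and stn1-226 exceeded that between rif1 deletion and wild type by 0.38 log2 (SE 0.08, adjusted p = 0.032). The rif1 deletion and wild type backgrounds differ, so background does not cancel in this last value. In its block 156 bins hold shared sequence and 11 none. The call of that block against stn1-226 was lost without 2 of the 8 libraries in turn. Each interaction was adjusted separately, and none was refitted with a library left out.

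In stn1-226 at 34 °C the 4 terminal blocks of chromosomes I and II held fewer ends than in wild type (-0.46 log2). A technical class is argued against, since the stn1-226 pair lay below the wild type pair in both classes, by -0.57 log2 in P and -0.35 log2 in Q. Reads shared between near-identical ends cannot be told apart from a loss: bins without shared sequence stood at -0.14 log2 (-0.21 and -0.07 in the pairs) once the right end of II was left out, and at -0.39 log2 with it, a value that met the bound set for exclusion, but its unshared bins stand at 2.15 log2 over the median in wild type, as copies missing from the assembly would give. A role of the restrictive temperature cannot be told apart from an effect at both temperatures, since 34 °C and 25 °C differed by -0.23 log2 (SE 0.13, adjusted p = 0.99). The strain background differs between stn1-226 and wild type and was not tested.

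In taz1 deletion the step fell at 437 of 520 sites. Low depth is argued against by 1 wild type library with fewer ends (8066894) than the least deep taz1 deletion library (8664614). The slope of its step on the consensus step of the libraries was 1.09, where the deepest taz1 deletion library (25702454 ends) had 0.20. A weak polymerase label is possible. The fine profiles of Pol delta and Pol epsilon had r = 0.93 and 0.88 in the taz1 deletion pairs against 0.35 to 0.68 elsewhere. Once each pair was divided by the SD of its polarity, 105 of the 437 sites kept their call and direction. Any genome-wide loss of steps lowers that SD, so the lost calls cannot tell a weak label from altered initiation. After that division the 8 sites with a pair of telomere-like motifs lay 0.42 log2 above the other sites (permutation p = 0.0005, adjusted p = 0.0024, 3 sites rose). Without the division they lay 0.39 log2 above and did not pass (adjusted p = 0.075). The 7 such sites called in wild type only, a choice that no mutant library enters, lay 0.29 log2 above without the division (adjusted p = 0.20) and 0.33 log2 above with it (adjusted p = 0.0076 over 2 tests). The division also enlarges values of taz1 deletion Pol delta replicate 2, which held next to no step signal. Initiation may be altered at some of the motif-pair sites, which would not account for the falls elsewhere. The source of the weak signal stays open.

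The libraries labelled stn1-226 rif1 deletion covered the rif1 gene at 1.10 and 1.09 times the median bin. Samples without a rif1 change are argued against by the correlation across sites with the change of rif1 deletion, whose lower value was r = 0.84, and a mixture with cells of an intact gene by the slope of that relation, at lowest 0.85. A disruption inside the gene cannot be told apart from an intact gene: in 0 of its 16 bins did all 8 libraries lie below all those of stn1-226. Compared library by library with stn1-226, which was chosen after the values were seen, the bin at chromosome I 2767201 to 2767500 was lower in 8 of 8 (mean -0.74 log2, SD 0.33) and the next, 2767501 to 2767800, in 7 of 8 (-0.41 log2, SD 0.66). No biological explanation was tested beyond the labelled genotype.

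Other splits of the libraries of each comparison into groups of the same size were refitted. For the comparisons other than taz1 deletion there are 18 splits, too few for a share under 0.05. For sites, the real value and the highest of the other splits were 39 and 3 in rif1 deletion 25 °C, 25 and 6 at 34 °C, 0 and 291 in stn1-226 25 °C, 0 and 0 at 34 °C, 35 and 227 in libraries labelled stn1-226 rif1 deletion against stn1-226 at 25 °C, 35 and 0 at 34 °C, and 0 and 0 in wild type between temperatures. For fork direction they were, in the same order, 97 and 9, 85 and 16, 0 and 160, 4 and 0, 96 and 93, 78 and 0, and 0 and 1 blocks. For total ends they were 0 and 123, 3 and 41, 0 and 128 in the comparisons of rif1 deletion at 25 °C and 34 °C and of libraries labelled stn1-226 rif1 deletion at 25 °C, 1 and 54 in stn1-226 25 °C, 4 and 4 at 34 °C, 1 and 7 in libraries labelled stn1-226 rif1 deletion at 34 °C, and 0 and 1 in wild type. In taz1 deletion, 100 splits were drawn. No other split drawn reached the real count for sites (437, highest other 385) or fork direction (145, highest other 99). That met the bound set for excluding chance. For total ends chance cannot be excluded (2, highest other 85, with as many in 17 of 100). The splits exchanged Pol delta and Pol epsilon libraries separately, although the 2 libraries of a pair share a class. With pairs as the unit there are too few splits for a share under 0.05, so chance is not excluded for sites and fork direction either.

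Splits with several times the real count point to structure among the samples. The 291 sites and 160 blocks came from stn1-226 25 °C Pol delta 1 and Pol epsilon 2 set together with wild type 25 °C Pol delta 2 and Pol epsilon 1, and the 227 sites and 93 blocks from stn1-226 25 °C Pol delta 1 and Pol epsilon 2 with Pol delta 1 and Pol epsilon 2 of the libraries labelled stn1-226 rif1 deletion 25 °C. Both cross classes Q and R between the polymerases. The counts of 123, 41, 128 and 85 blocks of total ends came from splits that set the Pol delta libraries of 1 condition with the Pol epsilon libraries of the other. A split that followed the class gave 17 blocks of total ends in the comparison of libraries labelled stn1-226 rif1 deletion 25 °C with stn1-226, where the real count is 0; within classes the 4 terminal blocks differed by 0.13 (Q) and 0.16 log2 (R). Splits that followed the class gave 0 sites.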

How the results depend on the processing

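The class as a block, limma on pairs, pairs scaled by polarity, the removal of doubted libraries, all 36 libraries in 1 fit, the crossed numbers, all places of a motif and the scaling at sites called in wild type were chosen after seeing the data. Outside the leave-one-out fits, 177 values under alternatives fixed earlier kept their direction and side of the threshold (or stayed within 1.5 times), 18 counts moved, 6 values reversed, 6 became stronger and 15 weaker; of the added ones 75 were kept, 10 moved, 4 became stronger and 1 weaker. Left-out libraries included, 1462 values of 83 named sites were kept, 329 were weaker and 1 reversed, and of 54 named blocks 947, 135 and 3. Where no construction is named, the cause was not tested.

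Sites changed numbered 39, 25, 35 and 35 in rif1 deletion 25 °C, rif1 deletion 34 °C, and the libraries labelled stn1-226 rif1 deletion at 25 °C and 34 °C. Flanks of 20 bins gave 66, 101 and 69 in all but the last. Flanks of 5 bins, which hold fewer ends, gave 21, 22 and 14 in all but rif1 deletion 34 °C, and sites called in wild type only gave 24, 21 and 23 there. Pol epsilon alone gave 0, 0, 0 and 4, and Pol delta alone 18 in the last. Only the groups compared gave 3 in rif1 deletion 34 °C and 6 in the libraries labelled stn1-226 rif1 deletion 25 °C. DESeq2 gave 93 and limma on pairs 71 in rif1 deletion 34 °C. The class as a block gave 109, 229, 106 and 70, and scaled pairs 202, 137, 102 and 123 (137 in taz1 deletion, from 437). Of the main calls, 39, 25, 33 and 32 were shared with limma on pairs and 34, 25, 35 and 35 with the class block, and all with scaled pairs. Leaving out 1 library gave 27 to 44, 11 to 163, 22 to 33 and 23 to 30 sites, 391 to 441 in taz1 deletion, and 0 in stn1-226 and wild type.

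Chromosome ends, fork direction: rif1 deletion 34 °C was weaker with blocks of 25 kb (-0.30), Pol delta (-0.40) or Pol epsilon alone (-0.071), only the groups compared (-0.23) and doubted libraries out (-0.27). The libraries labelled stn1-226 rif1 deletion 34 °C were stronger with blocks of 100 kb (-0.22), the class block (-0.15), limma on pairs (-0.15) and scaled pairs (-0.16). In wild type the value reversed with the bin filter (0.016) and Pol delta alone (0.016), and in stn1-226 34 °C with Pol epsilon alone (0.043). taz1 deletion was weaker with DESeq2 (-0.42), Pol delta (-0.66) or Pol epsilon alone (-0.18) and wild type 34 °C as control (-0.27). Left-out libraries gave -0.48 to -0.34 and -0.28 to -0.19 in rif1 deletion (25 °C, 34 °C), 0.03 to 0.18 and -0.12 to -0.05 in stn1-226, -0.56 to -0.46 and -0.19 to -0.12 in libraries labelled stn1-226 rif1 deletion, -0.16 to -0.01 in wild type and -0.49 to -0.34 in taz1 deletion.

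Total ends: stn1-226 34 °C was weaker with total-ends scaling (-0.43), blocks of 100 kb (-0.30), Pol delta alone (-0.28) and only the groups compared (-0.46), and stn1-226 25 °C stronger with DESeq2 (-0.23). The libraries labelled stn1-226 rif1 deletion 34 °C were stronger with DESeq2 (0.30), the bin filter (0.22), the replicate block (0.31) and the class block (0.31), and those at 25 °C stronger with Pol delta alone (0.58). Values reversed in rif1 deletion 34 °C with Pol delta alone (0.12), and with Pol epsilon alone in rif1 deletion 25 °C (-0.30) and libraries labelled stn1-226 rif1 deletion 25 °C (-0.31). taz1 deletion was weaker with blocks of 25 kb (0.51), Pol delta alone (0.93) and only the groups compared (0.80). Left-out libraries gave -0.0020 (without wild type 25 °C Pol delta 1, reversed) to 0.13 and -0.13 to -0.05 in rif1 deletion, -0.29 to -0.16 and -0.50 to -0.41 in stn1-226, 0.11 to 0.17 and 0.26 to 0.36 in libraries labelled stn1-226 rif1 deletion, 0.01 to 0.14 in wild type and 0.73 to 0.89 in taz1 deletion. A lone library left in a group is assumed to vary like the others. For the lists, sites called in wild type only lowered the Rif1 consensus differences in the 4 comparisons from 1.46, 1.24, 1.58 and 1.42 to 0.79, 0.45, 0.89 and 0.77, still past the test. In stn1-226 25 °C the consensus reversed at all its places (0.044, past the test). Values that reversed without passing were 8.4e-05 (consensus) and 0.018 (motif pair) in stn1-226 25 °C and 0.0010 (motif pair) in wild type with that choice, and 0.00057 at all pair places in stn1-226 25 °C. Of 42 list values, 26 were kept, 7 weaker, 4 stronger and 5 reversed. Among named items, III_2300101 (34 °C) reversed with flanks of 5 bins (0.019), and in taz1 deletion the blocks at chromosome II 1600201 (-0.015) and 1639801 (0.060) and at chromosome I 3779101 (0.079) reversed in direction with scaled pairs.

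The labels link replicates by number alone, and at 34 °C equal numbers also share the class and the reference. The replicate block gave 42, 47, 39 and 36 sites in the 4 comparisons. Deviations of same-numbered libraries had r of 0.88 and 0.85 for the libraries labelled stn1-226 rif1 deletion and stn1-226 at 25 °C, and -0.18 to 0.89 elsewhere except stn1-226 against wild type 25 °C (-0.90, -0.85). Crossing the stn1-226 25 °C numbers gave 0 sites, as without it (11 at an unadjusted p under 0.05). The least deep library has a median of 39 ends per bin, which limits single sites more than blocks of 50 kb.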

Other observations

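The tests of the resemblance in fork direction and of the scaled pairs were chosen only after the results were seen; the lists and the correlation test on Pol delta and Pol epsilon were not, while its Spearman values and the sites near the ends were added to it afterwards.

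Sites near tRNA genes had a lower mean change than other sites in the 4 comparisons with a labelled rif1 deletion. The 51 sites within 1 kb of a tRNA gene differed from other sites by -0.20 log2 at 25 °C and -0.22 log2 at 34 °C in rif1 deletion, and by -0.19 log2 at both temperatures in libraries labelled stn1-226 rif1 deletion (permutation adjusted p = 0.0036, 0.00049, 0.0045 and 0.0033). Of these sites 2, 2, 0 and 0 fell on their own (1, 17, 0 and 0 adjusted over the list alone). With the 53 such sites called in wild type only the differences were -0.17, -0.19, -0.14 and -0.15 log2 (adjusted p = 0.0025, 0.00048, 0.0029 and 0.0025). In stn1-226 the list differed by -0.01 log2 at 25 °C and by -0.04 log2 at 34 °C (adjusted p = 0.036), a call lost with sites called in wild type only (-0.03 log2, adjusted p = 0.084). At the ars1 site beside hus5 the values in the 4 comparisons with a labelled rif1 deletion were -0.37, -0.47, -0.34 and -0.15 log2, with a smallest adjusted p of 0.085, and at ars3002 beside ura4 they were 0.40, -0.01, -0.32 and -0.28 log2. The flank of the ars3002 site holds ura4, which was covered in part of wild type 25 °C and not in rif1 deletion, so the value of 0.40 is uncertain.

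In stn1-226 no single site passed, but lists differed slightly. At 34 °C the sites 50 to 100 kb from the ends of chromosomes I and II lay 0.17 log2 above the others (0.11 against -0.06, permutation p = 1e-05, the smallest that the draws can give, adjusted p = 5.3e-05), those within 50 kb lay 0.07 log2 above (adjusted p = 0.026), and those within 50 kb of a centromere -0.07 log2 below (adjusted p = 0.0033). At 25 °C the sites 50 to 100 kb from the ends differed by -0.10 log2 (adjusted p = 0.075) and the centromere sites by -0.12 log2 (adjusted p = 0.0033, and -0.06 with adjusted p = 0.060 in scaled pairs). The sites of high mean step differed by 0.23 log2 and those of low mean step by -0.22 log2 at 25 °C, and by -0.07 and 0.07 log2 at 34 °C. In scaled pairs these values were 0.02 and -0.04 at 25 °C and -0.03 and 0.03 at 34 °C, so most of the difference goes with the polarity of the pairs. In taz1 deletion the sites 50 to 100 kb from the ends lay 0.37 log2 above the others (9 of 15 fell, adjusted p = 0.017), and -0.05 log2 from them in scaled pairs (adjusted p = 0.74). There 3 of 4 within 50 kb fell and 3 of 3 near the ends of chromosome III fell.

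A hypothesis on the polymerases was tested across blocks. In rif1 deletion the change of total ends in the 4 terminal blocks was higher in Pol delta than in Pol epsilon, by 0.74 log2 at 25 °C and 0.43 at 34 °C, and in libraries labelled stn1-226 rif1 deletion by 0.89 and 0.10. The Pol delta share of ends may be higher where initiation rises: across 249 blocks, which are not independent, the Pol delta minus Pol epsilon change correlated with the mean step change at r = 0.30, 0.38, 0.32 and 0.29, the lowest 0.29 (Spearman 0.29, 0.44, 0.34 and 0.23). In stn1-226 r was 0.17 and 0.10 but Spearman 0.28 and 0.36, so by rank the relation is not particular to rif1 deletion, and in wild type between temperatures the values were -0.11 and -0.19. The 4 terminal blocks also moved apart by 0.34 log2 in stn1-226 at 34 °C, where no site passed. The sites within 50 kb of the ends did not rise in the 4 comparisons (mean change -0.05, -0.17, -0.08 and -0.03 log2), so whether the relation accounts for the chromosome ends stays open.

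Fork direction in stn1-226 at 34 °C might resemble that in rif1 deletion. Across 255 blocks the change had r = 0.37 with that of rif1 deletion at 25 °C, which shares no library, and r = 0.28 across the 239 blocks left without the outermost 4 of each arm of chromosomes I and II (Spearman 0.21). The value lies between the bounds set for and against, so the resemblance stays open.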
